A study of Morus alba var. atropurpurea with 6 samples.

How the data were processed

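RNA was extracted with Trizol from frozen fruit and 1 ug of total RNA per sample went into Illumina TruSeq libraries, per the labels' protocols, and was sequenced on a HiSeq 2000, per the series' design text. The TruSeq kit is named without any statement on strand. The submitters' processing notes name CASAVA. The aligner, the counting program, the reference build and the annotation are not given in the sources used here. The authors deposited 1 table per library with a gene identifier and an FPKM value, per the file headers. The deposited FPKM values are rounded to 2 decimals and the tables list only genes above 0. All identifiers begin with L484, and no source used here pairs them with names, so 0 of the 27 gene lists that had been fixed by product name, and no camera test, could be run. Whether the authors' counting split fragments between near-identical or overlapping genes is not stated. Some values are hard to read as whole fragments. L484_000092 had 0.01 FPKM in stage 2 replicate 2, beside 6.5 FPKM in stage 2 replicate 1. Values of genes that share fragments are therefore uncertain. Without gene coordinates, positions are not reported.

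Samples were grouped by their titles into control, stage 1 and stage 2 with 2 libraries each. No pair of libraries shared more than 59 identical values, so each counted as 1 sample. An exact permutation test of 2 against 2 libraries cannot go below a two-sided p of 0.333, so single values were not tested that way. Genes not listed in a library were set to 0. The test used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with all 6 libraries in 1 fit, group as the only term, and an intensity trend in the empirical Bayes step. Genes with at least 1 FPKM in at least 2 libraries (17945) were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute difference of at least 1. The fit had 3 residual and 2.54 prior degrees of freedom. Differences on this scale understate the fold of low genes. FPKM are not counts, so no count model was used.

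The genes named were fixed by rule: per comparison the 2 with the largest rise and the 2 with the largest fall among called genes with both libraries of one group above both of the other. The rule, the design and most alternatives were set before the data were examined. Alternatives were another pseudocount (0.1), other filters, 3 other scalings, no variance trend, a fit on the 4 libraries compared, a replicate block, no minimum fold and leaving out each library. A mean of at least 10 FPKM, library weights and levels from the stage 1 libraries alone were chosen after seeing the data.

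In 200 simulated genes changed by known amounts per comparison, with the residual spread of these data and 17945 genes tested, 46 of 50 genes changed by 2 log2 units were recovered for stage 1 against control, 45 of 50 for stage 2 against control and 46 of 50 for stage 2 against stage 1. At 1 log2 unit 8, 8 and 11 of 50 were recovered, and 8 unchanged genes were called in each. The changed genes were drawn only from genes above a minimum mean level and were only raised. Recovery of weaker genes and of falls was therefore not simulated.

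Depth was estimated with Python 3.11.15. A fragment counted whole adds the same step to a gene in a library, so the values of a gene up to 10 FPKM would then be whole multiples of its step. Library factors were searched for that placed the most genes on such steps in at least 3 libraries, with at most 25 fragments per value and a tolerance of at most 0.12 steps. The factors found placed 1212 genes on steps, against at most 40 for 10 random sets of factors. The search maximized this number and the random sets were not searched, so part of the gap follows from the search. The bootstrap SD of the factors was at most 0.0003 in log2, which covers the choice of genes only. In 3 simulated sets, which held whole fragments only, the largest error was 0.0006 in log2. Absolute fragment numbers per library remain unknown, so no counting interval or floor is given, and the steps show depth relative to control replicate 1 only. They measure the fragment total behind the FPKM values and not the reads sequenced, so a share lost to fungal reads could not be told from shallower sequencing.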

Results

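Gene expression was measured by RNA sequencing in mulberry (Morus alba var. atropurpurea) fruit, a compound fruit built of many small achenes, with and without infection by Ciboria carunculoides, an ascomycete fungus that makes mulberry fruit swell. The 6 libraries form 3 groups of 2 libraries each, namely untreated control fruit, stage 1 fruit, in which part of the fruit protruded and single achenes were swollen, and stage 2 fruit, in which the achene had browned. The values were FPKM per gene, a fragment count scaled to transcript length and to the mapped fragments of the library, as the authors deposited them. The 6 libraries together listed 21747 genes, of which 15541 were listed in every library. The number of genes listed was 19987 and 20004 in the control libraries, 19387 and 19027 at stage 1, and 17537 and 17161 at stage 2. The number with at least 1 FPKM was 16865 and 17102 in control, 16902 and 16522 at stage 1, and 15605 and 15445 at stage 2.

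Gene identifiers were L484 locus tags without product names, so gene families and pathways could not be assigned, and gene groups are described here by level and by course over the 3 groups. Total fragment counts are not given in the files, but in 1212 genes the low FPKM values fell on steps of whole fragments, which gave the depth of each library relative to control replicate 1. Other low values did not fall on such steps within the rounding and limits used. Control replicate 2 had 83.0% of that depth, the stage 1 libraries 52.0% and 47.1% (replicates 1 and 2), and the stage 2 libraries 23.1% and 19.3%. Depth therefore fell in the same order as disease advanced. Depth here means the fragment total to which the FPKM of a library were scaled, not the reads sequenced. How many reads of infected fruit came from the fungus is not given. Whether they lowered this total, or were counted in mulberry genes, could not be tested. Low values at stage 2 rest on fewer fragments than in control, and an unlisted gene there means not detected at this depth.

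**Figure D1:**
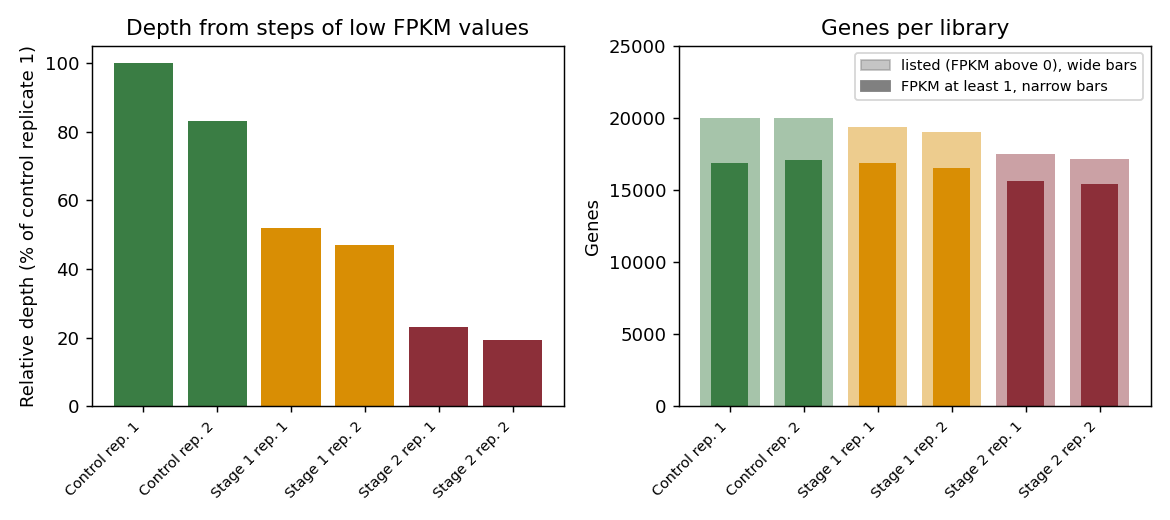
Left, relative depth of the 6 libraries in percent of control replicate 1, from the steps of low FPKM values; right, genes listed (wide pale bars) and genes with at least 1 FPKM (narrow bars) per library, with colours marking control, stage 1 and stage 2. The stage 2 libraries, at 23.1% and 19.3% of the depth of control replicate 1, listed 17537 and 17161 genes.

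Libraries of one group were compared first. Over the 17945 genes tested, the Pearson correlation of log2(FPKM + 1) across genes was 0.939 between the control libraries, 0.945 between the stage 1 libraries and 0.912 between the stage 2 libraries. Between control and stage 2 libraries it was 0.791 to 0.812, and between stage 1 and stage 2 libraries 0.840 to 0.870. Control replicate 2 reached 0.919 and 0.9 with the stage 1 libraries, and control replicate 1 reached 0.877 and 0.868. In genes with a mean of at least 10 FPKM these values were 0.881 and 0.838 for control replicate 2 and 0.789 and 0.763 for control replicate 1. The stage 2 pair reached 0.917 in those genes, above control replicate 2 with stage 1. The first principal component (52.8% of the variance) separated both stage 2 libraries from the other 4. The second component (20.2%) separated the stage 1 libraries from control, with control replicate 2 at 14.25 lying between control replicate 1 at 58.99 and the stage 1 libraries at -48.17 and -50.88. Nothing in the labels says whether libraries of one group came from separate plants, so the p-values below measure only the spread between these samples.

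**Figure D2:**
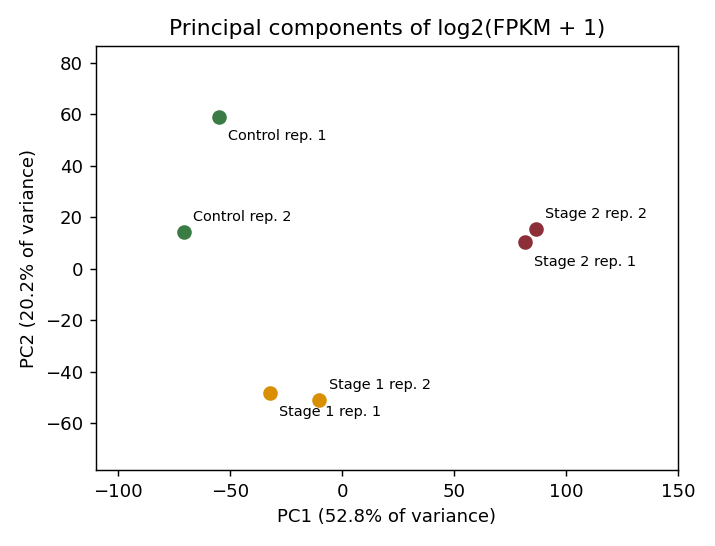
First against second principal component of log2(FPKM + 1) over 17945 genes, 1 point per library, coloured by group. The stage 2 libraries sit at 81.58 and 86.65 on the first component, and the other 4 libraries lie between -70.79 and -10.13.

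The first comparison asked which genes differed once the achenes had swollen. At stage 1, 134 genes rose and 49 fell against control (adjusted p under 0.05 and a difference of at least 1 in log2(FPKM + 1), limma with Benjamini-Hochberg adjustment). L484_008826 rose from 0.53 FPKM in control replicate 2 and unlisted in control replicate 1 to 30.31 and 59.74 FPKM at stage 1 (log2 difference 5.14, SE 0.49, adjusted p = 0.0376). L484_010360 rose from 14.8 ± 0.099 to 436.9 ± 13.5 FPKM (mean ± SD, n = 2; log2 difference 4.79, SE 0.43, adjusted p = 0.0376 in limma). L484_023597 fell from 24.42 and 16.82 FPKM to 0.01 FPKM in stage 1 replicate 1 and unlisted in replicate 2 (limma adjusted p = 0.0358). L484_006593 fell from 19.51 and 7.84 FPKM to unlisted in both stage 1 libraries (limma adjusted p = 0.0441). With a pseudocount of 0.1 in place of 1, limma called 54 genes instead of 183, and L484_008826 (adjusted p = 0.0559) and L484_006593 (adjusted p = 0.0538) did not pass.

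Most risers at stage 1 had moderate to high means over all 6 libraries, the diseased ones included. A rise itself lifts that mean, so the mean does not show the level of these genes in control fruit. Of the genes with a mean of 20 to 100 FPKM over the 6 libraries, 65 rose and 19 fell. Among those with 100 FPKM or more, 28 rose and 9 fell, which is 4.29% of the 862 genes at that level. Of the 6538 genes under 5 FPKM, 6 rose and 10 fell. A rise or fall of at least 3 in log2(FPKM + 1) was reached by 16 of the genes that rose and 7 of those that fell. Counting without a model, 511 genes had both stage 1 libraries at least 1 log2 unit above both control libraries, and 480 had them at least 1 unit below. The other pairings of the same 4 libraries gave 119 and 157 such genes in either direction, against 991 for the study groups. By chance alone 2 libraries against 2 fail to overlap in 33.3% of genes, before any minimum difference is asked.

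The modelled stage 1 calls depended on single libraries. With control replicate 1 or either stage 1 library left out, limma called 0 genes, with 1999, 2381 and 1906 genes at an unadjusted p under 0.05 (control replicate 1, stage 1 replicate 1 and stage 1 replicate 2 left out), against 3252 with all 6 libraries. With either stage 2 library left out 1 gene was called, and with control replicate 2 left out 196 were called, 61 of them shared with the 183 calls from all libraries.

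The second comparison set browned fruit against control fruit and gave the most calls of the 3. At stage 2, 1164 genes rose and 2031 fell. Large changes were common, with 160 genes rising and 208 falling by at least 3 in log2(FPKM + 1). L484_008826 again rose most, to 94.32 and 198.57 FPKM (log2 difference 6.80, SE 0.49, limma adjusted p = 0.00425). L484_018126 rose from 1.35 FPKM in control replicate 1 and unlisted in control replicate 2 to 87.28 and 104.59 FPKM (log2 difference 5.98, SE 0.43, limma adjusted p = 0.00425). A fall on this scale cannot exceed the control value, so the largest falls could only be in genes abundant in control fruit. L484_000135 stood at 765.27 and 1301.05 FPKM in control and was unlisted in both stage 2 libraries (limma adjusted p = 0.00497). L484_008276 fell from 381.5 ± 113 to 0.915 ± 0.66 FPKM (mean ± SD, n = 2; log2 difference -7.65, SE 0.69, limma adjusted p = 0.00497).

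Direction at stage 2 went with expression level in values as deposited. Among genes with a mean of 100 FPKM or more 162 rose and 99 fell (62.1% rises), and 30.3% of that group was called. Rises also outnumbered falls at this level under the other scalings, with 187 against 76 after median ratio scaling, 147 against 115 after quantile normalization and 148 against 108 after scaling to equal sums. From 20 to 100 FPKM the numbers were 403 and 452. From 5 to 20 FPKM they were 383 and 782, and under 5 FPKM they were 216 and 698, so that 23.6% of the calls among the weakest genes were rises. The excess of falls under 5 FPKM held after median ratio scaling (249 rises, 584 falls) and turned after quantile normalization (398 rises, 253 falls), and from 20 to 100 FPKM the balance turned after median ratio scaling (504 rises, 353 falls). These levels are means over all 6 libraries, stage 2 included. With levels from the stage 1 libraries alone, rises were 28.9% of calls under 5 FPKM and 60.2% at 100 FPKM or more as deposited, and 36.1% and 70.3% after median ratio scaling. A group of 37 genes had at least 10 FPKM in both control libraries and was unlisted in both stage 2 libraries, while 3 genes showed the reverse.

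The overall balance of rises and falls at stage 2 depended on the scaling of the libraries. Rises were 36.4% of calls with FPKM as deposited, 46.7% after scaling by the median ratio of each library to the mean library, 51.5% after quantile normalization and 32.4% after scaling to equal sums. The median log2 difference of all genes was -0.23 as deposited, -0.09 after median ratio scaling and 0 after quantile normalization. With control replicate 1 left out 1693 genes were called, and with control replicate 2 left out 1206, of which 616 rose and 590 fell.

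**Figure D3:**
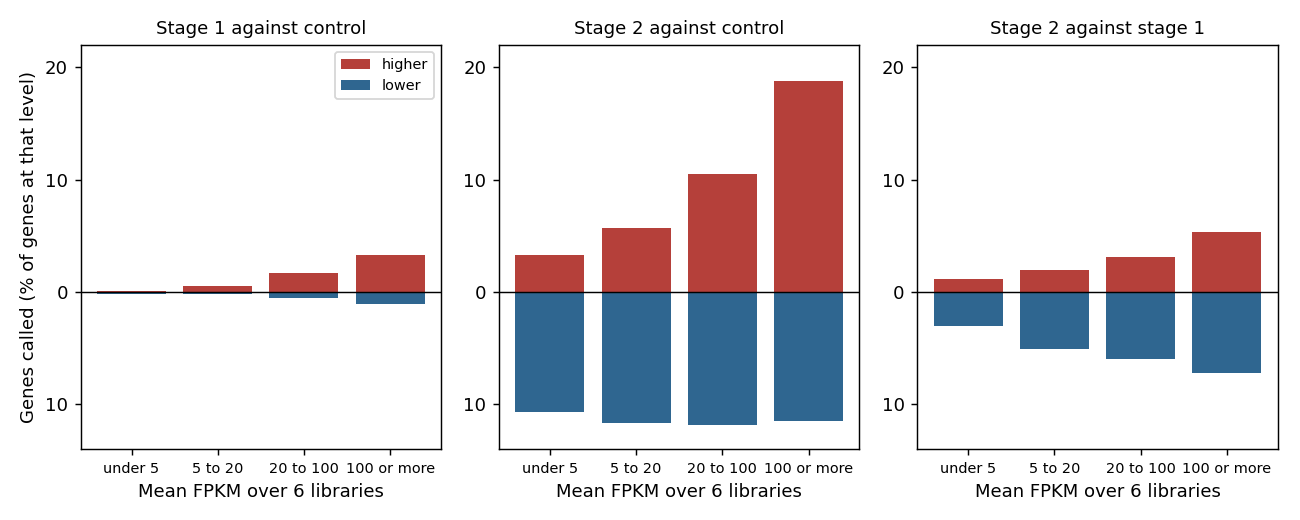
Genes called higher (upward bars) and lower (downward bars) in each comparison, in percent of the genes at 4 levels of mean FPKM over the 6 libraries. At stage 2 against control rises grow with level, to 162 of 862 genes at 100 FPKM or more, while falls outnumber rises below 100 FPKM with values as deposited; quantile normalization turns this balance under 5 FPKM and median ratio scaling turns it from 20 to 100 FPKM.

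With all 6 libraries in the fit, most genes called at stage 1 were also called at stage 2. Of the 134 genes that rose at stage 1, 116 also rose at stage 2 and 18 did not pass the test there. Of the 49 that fell, 40 also fell and 9 did not pass. No gene was called in opposite directions at the 2 stages, and 156 were called in the same direction. This overlap of 156 rests on the stage 1 calls. In limma it was 0 with control replicate 1 or either stage 1 library left out, 1 with either stage 2 library left out, 160 with control replicate 2 left out, 48 with a pseudocount of 0.1 and 418 with library weights. Where it was 0, 1906 to 2381 genes had an unadjusted p under 0.05 at stage 1. Both stages were compared with the same control libraries. Independent lists of these sizes would share 8.69 rising and 5.55 falling genes, and 50 simulated sets with no effect against shared controls gave 0 genes called alike, a number that says nothing of what shared controls add to lists of real calls, since sets with no effect hold almost none. The covariance of the log2 differences across genes was 0.443, against 0.079 simulated from the shared controls alone (correlations 0.565 and 0.5). The 2 control libraries were not split between the stages, so part of the overlap may come from sharing them. A further 1048 genes rose and 1991 fell at stage 2 without passing the test at stage 1, which does not show that the stages differed in these genes.

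The third comparison tested stage 2 against stage 1 directly. From swollen to browned achenes 370 genes rose and 829 fell (30.9% rises, against 44% after quantile normalization). L484_018126, unlisted in both stage 1 libraries, rose to 87.28 and 104.59 FPKM (limma adjusted p = 0.0115). L484_021179 rose from 1.82 ± 1.1 to 150.9 ± 93 FPKM (mean ± SD, n = 2; log2 difference 5.66, SE 0.54, limma adjusted p = 0.0149). L484_000135 fell from 243.29 and 33.23 FPKM to unlisted in both stage 2 libraries (limma adjusted p = 0.0273). L484_010361 fell from 239.07 and 102.45 FPKM to 5.31 FPKM and unlisted (limma adjusted p = 0.0350).

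Of the genes that rose at stage 2 against control, 289 also rose against stage 1, and of those that fell, 638 also fell against stage 1. In 636 of the 1164 risers and 1051 of the 2031 that fell, both stage 1 libraries lay between the control and the stage 2 libraries. Stage 1 libraries no different from control would both lie on the stage 2 side of both control libraries in 16.7% of genes by order alone, and more often in genes chosen for a wide gap. The named genes followed different courses. L484_008276 went from 381.5 FPKM in control through 60.1 at stage 1 to 0.915 at stage 2. L484_010360 was highest at stage 1, with 158.6 ± 100 FPKM at stage 2 (mean ± SD, n = 2), and its difference between the stages did not pass the test (limma adjusted p = 0.0758). L484_023597, near 0 at stage 1, stood at 9.47 and 13.18 FPKM at stage 2, a rise over stage 1 (limma adjusted p = 0.0115).

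The calls between the stages rested on the stage 1 and stage 2 libraries. With either stage 1 library or stage 2 replicate 2 left out limma called 0 genes, with 3104, 3758 and 4925 genes at an unadjusted p under 0.05 (stage 1 replicate 1, stage 1 replicate 2 and stage 2 replicate 2 left out), against 5362 with all 6 libraries. With stage 2 replicate 1 left out 280 genes were called. With control replicate 1 left out 1035 genes were called and with control replicate 2 left out 994, of which 799 and 784 were shared with the 1199 calls from all libraries.

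**Figure D4:**
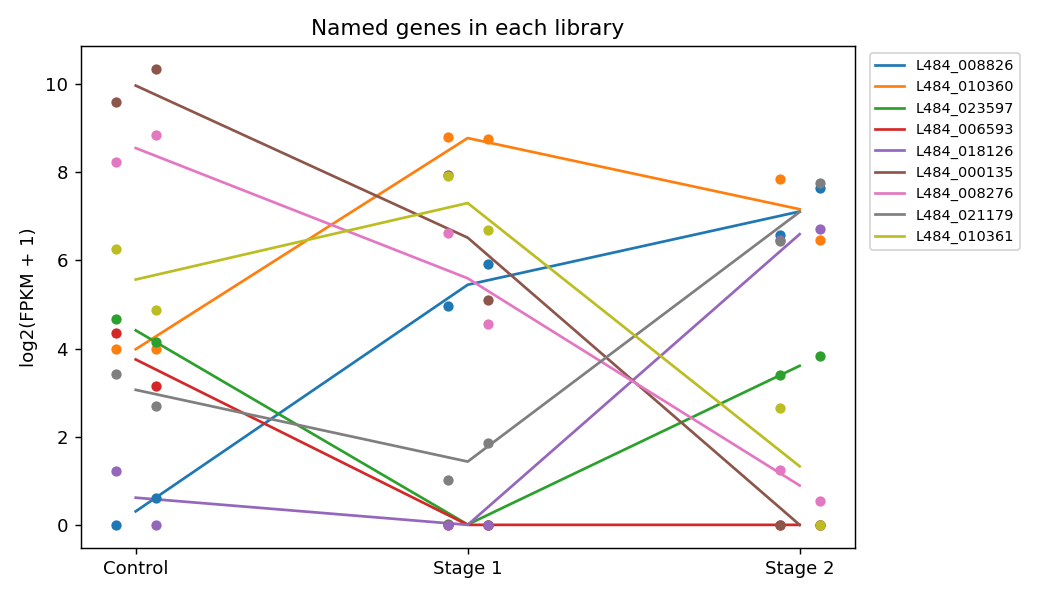
log2(FPKM + 1) of the 9 named genes in each library (points, 2 per group) with lines through the group means. L484_000135 and L484_008276 decline from control to stage 2, L484_008826 climbs, and L484_023597 is near 0 at stage 1 alone.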

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

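The test between the stages was set before the data were examined, and the depth comparison of unlisted genes had its bounds set before its result was seen, whereas its allowances for spread and scaling, the simulated sets and both tests of rises and falls were chosen after. The change against control differed between stage 2 and stage 1 in 1199 genes by the direct test of the stages (limma, adjusted p under 0.05 and a difference of at least 1). Among the named genes the difference, stage 2 minus stage 1 in log2(FPKM + 1), was 3.60 for L484_023597, 6.59 for L484_018126, -6.51 for L484_000135, -4.70 for L484_008276, 5.66 for L484_021179 and -5.97 for L484_010361. These sizes depend on the pseudocount and are no bound where a library was unlisted (L484_023597 and L484_018126 at stage 1, L484_000135 and L484_010361 at stage 2), and with a pseudocount of 0.1 the difference of L484_010361 was -7.73 and did not pass the test (limma adjusted p = 0.0691). L484_023597 is the one named gene that was near 0 at stage 1 alone, with 20.6 FPKM in control and 11.3 at stage 2. Its 0.01 FPKM in stage 1 replicate 1 is also very small for a whole fragment, so its values may be uncertain. No group was large enough to test for a single outlying library.

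Stage 2 libraries listed fewer genes, and they were also the shallowest. In 295 genes with recovered fragment numbers and at least 10 control fragments, 197 gene values were unlisted over the 2 stage 2 libraries, against 118.4 expected from the control level at the stage 2 depth (SD 9.5), a ratio of 1.66. This narrowly passes the bound of 1.5 set against lower depth as the whole cause. In 20 sets simulated with no change the ratio was 0.79 to 0.94, or 0.81 to 1.04 with the spread of the widest replicate pair added. Lower depth may thus account for a large part of the unlisted values in these genes. With values as deposited and counting noise alone it is argued against as the whole cause. The expected number is 131.5 with that spread (ratio 1.5), 140.6 with median ratio scaling (1.4) and 153.1 with both (1.29). None of these ratios passes the bound, so with these allowances it gives no verdict. Library scaling stays open for part of the excess, as does a loss of expression in browned fruit, which was not tested otherwise.

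Falls outnumbered rises at stage 2. Rises were 36.4% of calls as deposited, 46.7% after median ratio scaling and 51.5% after quantile normalization, so scaling stays open as the cause of this excess. For the difference between expression levels, a single scaling factor per library is argued against as the whole cause. With levels from the stage 1 libraries, which are on neither side of the comparison, rises after median ratio scaling were 36.1% of calls under 5 FPKM and 70.3% at 100 FPKM or more, 34.2 points apart; quantile normalization, which makes all distributions equal, turned the balance under 5 FPKM to 63.6% rises. Lower depth pulls down the log values of weak genes but leaves their summed FPKM unmoved. After median ratio scaling that sum, over 7016 genes with a stage 1 mean under 5 FPKM, was 0.914 times control at stage 2 (bootstrap SD over genes 0.018). It was 0.896 and 0.933 in the stage 2 libraries, against 1.043 and 0.957 in control replicates 1 and 2. The bootstrap does not cover this spread between libraries. In 20 sets simulated with no change the ratio was 0.987 to 1.011. The stage 2 sum lies below all simulated sets and below 0.95, the lower edge of the range set for noise alone. It does not reach the bound of 0.85 set against noise, and the control libraries also differed. Lower depth therefore stays open, as does a fall of weak genes with disease, which was not tested otherwise.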

How the results depend on the processing

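The mean-FPKM filter and the library weights were chosen after seeing the data; other settings were planned. The stage 2 against control count (3195) stayed within 1.5 times under all planned settings except a fit on the 4 libraries compared (1959) and leaving out single libraries (1206 to 2360; 1693 without control replicate 1 and 1206 without control replicate 2), and was 1832 with a mean of at least 10 FPKM. The stage 1 against control count (183) was 54 with a pseudocount of 0.1, 391 with the filter at 5 FPKM, 516 with genes above 0 in all 6 libraries, 407 after quantile normalization, 89 without the variance trend, 1 in a fit on the 4 libraries compared, 443 with a mean of at least 10 FPKM, 548 with library weights, and 0 to 196 with single libraries left out. The stage 2 against stage 1 count (1199) was 774 without a filter, 380 in a fit on the 4 libraries, 772 with library weights, and 0 to 1035 with single libraries left out. The overlap of the stages (156) was 48 with a pseudocount of 0.1, 369 with a mean of at least 10 FPKM, 418 with library weights, and 0 to 160 with single libraries left out. Leaving out a library takes away 1 residual degree of freedom and rests the lone library's spread on the other groups; beyond that the cause was not tested. Counts of 0 came from limma, the one tool run, with 1906 to 3758 genes at an unadjusted p under 0.05 where a library of the groups compared other than stage 2 replicate 2 was left out, and 4925 without that library. The replicate block gave 2 calls at stage 1, 2562 at stage 2, 185 between the stages and an overlap of 2. Libraries with the same number did not deviate together across genes (correlations -0.08, 0.011 and -0.012). That cannot show whether they shared a plant or day, and the labels do not say, so the blocked fit tests no known pairing. Rises were 73.2% of calls at stage 1 as deposited, 80.5% after median ratio scaling and 68.6% after quantile normalization, and 30.9%, 40.7% and 44% between the stages. Of 118 alternative values of the named genes 80 kept the call and 38 lost it, none of these at stage 2 against control. None changed sign, but this is no support. The genes were chosen for separated libraries and the largest differences, so their signs could hardly change. L484_006593 had no value without either control library, where the filter removed it. Genes at or above 0.1 FPKM numbered 19655 and 19756 in control, 19271 and 18935 at stage 1, and 17505 and 17132 at stage 2; at 5 FPKM they numbered 11537 and 11570, 11326 and 11077, and 10538 and 10423. The gene list alternatives were not run, since no list could be formed.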

Other observations

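The tests of control replicate 2 in this part were chosen after the result was seen. The set of most abundant genes differed between libraries, within control as well as between groups. Of the 100 genes with the highest FPKM in each library, 43 were common to all 6 libraries. The stage 1 libraries shared 87 of their 100 and the stage 2 libraries 88, but the control libraries shared 74. Control and stage 2 libraries shared 55 to 61. Control replicate 1 shared as few with the stage 1 libraries (61 and 60), and control replicate 2 shared 78 and 71. The 10 highest genes held 4.91% and 4.08% of summed FPKM in control, 4.8% and 5.5% at stage 1, and 7.01% and 7.75% at stage 2, and the highest single value was 3501.04 FPKM in control and 6837.15 FPKM at stage 2.

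Genes in which one group stood apart from both others by at least 16-fold were few. With at least 10 FPKM in all libraries of the other groups, 11 genes were lower at stage 2 alone, and 8 of these were unlisted in both stage 2 libraries. In the other direction, 3 genes were higher at stage 2 alone and 1 at stage 1 alone, 2 were lower in control alone, and none was lower at stage 1 alone or higher in control alone at these limits.

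Control replicate 2 lay nearer to stage 1 than control replicate 1 did, sharing 78 and 71 of its 100 most abundant genes with the stage 1 libraries, against 61 and 60 for control replicate 1. Noise in weak genes is argued against, since in genes with a mean of at least 10 FPKM the SD of the log2 difference to stage 1 replicate 1 was 0.884 for control replicate 1 and 0.665 for control replicate 2, a gap of 0.219. Stage 1 material mixed into control replicate 2 is argued against as the whole cause only if the median share below is its true share. That median was 0.2 over 46 genes at least 10-fold higher at stage 1 than in control replicate 1, a choice of genes that raises the share. Single genes varied widely, with quartiles of 0.08 and 0.47 over 48 genes as deposited. Mixing at the median share would lower other genes by at most 0.33 in log2. In 62 genes at least 4-fold lower at stage 1 than the geometric mean of both control libraries, control replicate 2 over control replicate 1 had a median log2 of -0.94. This lies a further -0.61 from that value (bootstrap SD over genes 0.12, median ratio scaling). The bootstrap does not cover the spread between libraries. Toward stage 2 the order was reversed. Control replicate 2 shared 55 and 57 of its 100 most abundant genes with the stage 2 libraries, against 61 and 60 for control replicate 1. Its correlations of log2(FPKM + 1) with the stage 2 libraries were 0.792 and 0.791, against 0.812 and 0.81. A difference in ripeness or an early infection of that fruit may be the source of the nearness to stage 1, and neither was tested.

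Genes with consecutive identifier numbers changed alike slightly more than chance. Across 12230 such pairs, which are not independent replicates, the correlation of the stage 2 against control differences was 0.104 (permutation p = 0.001, the smallest that these permutations can give, adjusted p = 0.0017 over 5 such tests), and -0.005 for numbers 50 apart. The stage 1 against control differences gave 0.085 (permutation p = 0.001, adjusted p = 0.0017), and the difference between the control libraries gave 0.063 with the same p. The differences between libraries gave 0.022 within stage 1 (permutation p = 0.012, adjusted p = 0.015) and 0.019 within stage 2 (permutation p = 0.031, adjusted p = 0.031).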
